A study of Mus musculus with 7 samples.

How the data were processed

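RNA was measured by Smart-seq2, a full-length cDNA protocol for small cell numbers, in haematopoietic stem cells (HSCs) sorted from mouse bone marrow. Each of the 7 libraries came from 150 sorted cells and was sequenced as paired-end reads of 100 bp. Per the labels, 3 libraries were Cre-negative controls and 4 were Mx1-cre; Mettl3 fl/fl mutants. All animals received 5 injections of 10 µg pIpC, a double-stranded RNA analogue that induces Cre from the Mx1 promoter through interferon, and cells were taken 10 days after the last injection.

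The values used were the deposited RPKM (reads per kilobase of gene model, scaled to library size), in 2 columns that hold 1 value per gene and group, per the file headers. The authors had pooled the libraries of each group into a group mean, so no spread between libraries could be computed, no SD, standard error or p-value is given, and no difference has a replicate check. Per the submitters' processing notes, the genome build was mm10 and the tools included Picard and edgeR; their roles, the aligner, the gene annotation and the way of averaging are not given in the sources used here. An edgeR test of the 7 libraries had been planned before the data were examined, and it was replaced because the deposited RPKM are group means and not counts. Coordinates are those of NCBI RefSeq on GRCm38.p6, the assembly that mm10 names. The table held 23038 genes by NCBI Gene identifier and symbol, and 22959 of the identifiers (99.7%) were in RefSeq.

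The deposited RPKM included a small offset. In 8499 genes (36.9%) the mutant/control ratio was 0.841, and each value was a constant of its group divided by a whole number of bases (tolerance 1e-05 bases, or the rounding of the table where that was wider). The constants amount to 0.0414 RPKM in controls and 0.0349 RPKM in mutants for a gene of 1 kb. Of these genes, 7641 had a symbol in GENCODE M21, and for 2532 (33.1%) the implied length equalled that of an annotated transcript, against 6 when 100 bases were added to it. The values were therefore read as means over libraries of reads plus 1, divided by gene length and library size, and a gene at the offset as a gene without reads. In genes at the offset in a single group, step sizes were sought among the most frequent small excesses in the other group. Their number was set to that of the libraries, 3 in controls and 4 in mutants. Their sum was required to be 1 offset, so neither the number nor the sum tests this reading of the values. If a step is 1 read, the library sizes were 19.6 M, 24.3 M and 31.1 M reads in controls and 25.7 M, 26.9 M, 27.2 M and 37.7 M reads in mutants (M, megareads). These sizes could not be tied to individual animals. A gene was called carried by a single library when its excess was a whole number of steps of 1 library (relative tolerance 1e-07). A simulated table of 23038 genes with known reads was made with the same formula, so it checks the procedure and not the reading of the values. The procedure recovered 100% of the genes without reads and 100% of the single-library genes of either group. It read 0 of 406 mutant and 0 of 208 control genes with several libraries as single, and wrongly put 5 genes at the offset in 1 group.

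Differences are given as log2((mutant + 1) / (control + 1)), with a pseudocount of 1 RPKM, a scale that understates the change of low genes. Folds of named genes are ratios of the deposited means. Genes were counted as apart when they differed at least 2-fold on the pseudocount scale, a rule of size and not a test. The 29 gene lists were written before the data were examined. For each list with at least 5 members above the offset, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins, and a list was called outside when it fell beyond the central 95%. This percentile describes these 2 columns and is not a p-value. In lists of 30 genes drawn at random from the real values, 5% of 100 lists with no added shift fell outside. That share is set near 5% in advance, because the random lists come from the same values. With a log2 shift of 0.2 the share was 43%, and with 0.4 it was 99%. Genes of the fixed lists can vary together, so these shares need not hold for them. Lists of fewer genes were not simulated. The simulation also left out the lowest genes and used fewer random lists. The lists of sex-linked, basophil or mast cell and mitochondrially encoded genes were not compared with random lists.

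The planned rule for named genes needed p-values. It was replaced, after the values were seen, by the 12 genes with the highest and the 12 with the lowest log2 ratio among genes with at least 10 RPKM in 1 of the groups, leaving out predicted genes and pseudogenes. The rule also took Mettl3, Myc, Cdkn1a, Ifit1 and Itga2b, the 4 members farthest apart of each list outside the random range and the 2 members farthest apart of each other list, and together these made 88 genes. Some genes that the rule takes are not reported here. A pseudocount of 0.1 RPKM was planned as an alternative. Chosen after seeing the data were a minimum of 1 RPKM in at least 1 group, 2 rescalings of the mutant column, no pseudocount, leaving out genes carried by a single library, leaving out immediate early genes from the other lists, and the mean in place of the median. Computations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots matplotlib 3.10.9.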

Results

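Transcript levels were compared between HSCs of mice with induced deletion of Mettl3, the catalytic subunit of the complex that places N6-methyladenosine (m6A) on mRNA, and HSCs of Cre-negative controls, to ask which transcripts differ in stem cells 10 days after the last injection of the inducer. HSCs were sorted as lineage-negative, Sca1-positive, cKit-positive, CD150-positive and CD48-negative cells from C57BL/6 mice, with 3 control and 4 mutant libraries of 150 cells each. The values are the authors' group means in RPKM, 1 per gene and group, with no spread between animals, so every difference below is a difference between 2 means that has no replicate check. Library sizes read from the steps of the low values ran from 19.6 M to 31.1 M reads in controls and from 25.7 M to 37.7 M in mutants. At these sizes 1 RPKM on a gene of 1 kb corresponds to between 19.6 and 37.7 reads in a library. Of 23038 genes, 14539 had reads in at least 1 group and 10502 had at least 1 RPKM in both. The median log2 mutant/control ratio of the latter was 0.02, and the column sums were 503762 RPKM in controls and 499616 RPKM in mutants.

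Mettl3, the targeted gene (NCBI Gene 56335, chromosome 14, 52294841 to 52308741, GRCm38.p6), was at 49.8 RPKM in controls and 9.60 RPKM in mutants, 19.3% of the control level and a log2 difference of -2.26. The value covers the whole gene model, and which exons the floxed allele removes is not given in the sources used here. Of the 20 other components of the m6A machinery, 16 were higher and 4 lower in the mutant mean. On the pseudocount scale, the largest differences were in Ythdf2 and Rbm15. Ythdf2, a cytoplasmic m6A reader that promotes decay of its targets, was at 63.0 RPKM in controls and 127 RPKM in mutants. Rbm15, an adaptor of the methyltransferase complex, was at 8.84 and 16.7 RPKM. By the ratio of the deposited means, Ythdc2 was farthest apart, 2.28-fold higher at 1.34 and 3.06 RPKM. Igf2bp2, 1 of the 4 lower genes, was at 6.81 and 3.42 RPKM. The median log2 ratio of the machinery was 0.21 (percentile 93.5 among random lists), inside the central 95%.

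Across all genes, 534 were at least 2-fold higher and 504 at least 2-fold lower in the mutant mean, 1038 together or 7.14% of the genes with reads. Among the 6607 genes with at least 10 RPKM in 1 of the groups, 222 were at least 2-fold higher and 163 lower. The counts depend on the pseudocount: with 0.1 RPKM in place of 1, there were 1508 higher and 1347 lower genes.

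**Figure D1:**
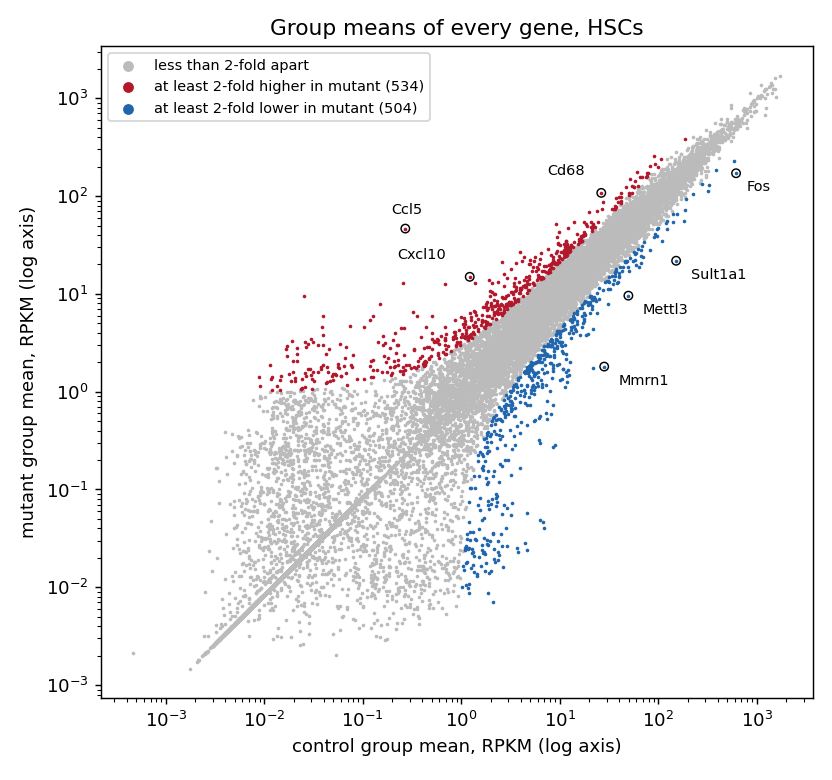
Mutant against control group mean of every gene in RPKM, both axes logarithmic, 1 point per gene, with the 534 genes at least 2-fold higher in red and the 504 at least 2-fold lower in blue on the log2(RPKM + 1) scale. Mettl3 lies at 49.8 RPKM in controls and 9.60 RPKM in mutants, and the narrow diagonal at the lower left holds the 8499 genes at the offset in both groups.

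The gene farthest apart was Ccl5, a chemokine that attracts T cells and monocytes (chromosome 11, 83525778 to 83530518), with 0.270 RPKM in controls and 46.6 RPKM in mutants. Cxcl10, a chemokine induced by interferon, was at 1.22 and 15.0 RPKM, and Mdk, which encodes the heparin-binding growth factor midkine, at 0.685 and 12.5 RPKM. The polo-like kinase gene Plk3 was 8.16-fold higher in the mutant mean, at 21.3 RPKM. Vps33a, which encodes a subunit of the complexes that tether endosomes and lysosomes, was at 9.21 RPKM in controls and 51.3 RPKM in mutants, and Mrs2, a magnesium channel of mitochondria, at 4.12 and 21.8 RPKM. The other 6 of the 12 genes highest in the mutant relative to the control were Qsox2, Lipt1, Tspan17, Lrr1, Zfp948 and Sgsm3, with mutant means between 12.8 RPKM for Lrr1 and 18.1 RPKM for Zfp948.

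Among the genes lower in the mutant mean, Mmrn1, which encodes a protein of platelet granules and endothelium (chromosome 6, 60944317 to 60989378), was at 28.3 RPKM in controls and 1.81 RPKM in mutants. Sult1a1, a sulfotransferase gene (chromosome 7, 126672865 to 126690443), was at 152 and 21.8 RPKM, 6.96-fold lower. Tnfrsf25, a receptor of the tumour necrosis factor family, was 12.6-fold lower, and Gfpt2, an enzyme of hexosamine synthesis, was 8.32-fold lower. Oas1c, of the oligoadenylate synthetase family, was at 11.9 RPKM in controls and 1.25 RPKM in mutants, although most interferon response genes were higher in the mutant mean. Besides Mettl3, the rest of the 12 lowest genes were Ccdc17, Tspan8, Atf3, Cldn10, Mfsd12 and Rapsn, with control means between 10.0 RPKM for Rapsn and 12.1 RPKM for Cldn10.

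**Figure D2:**
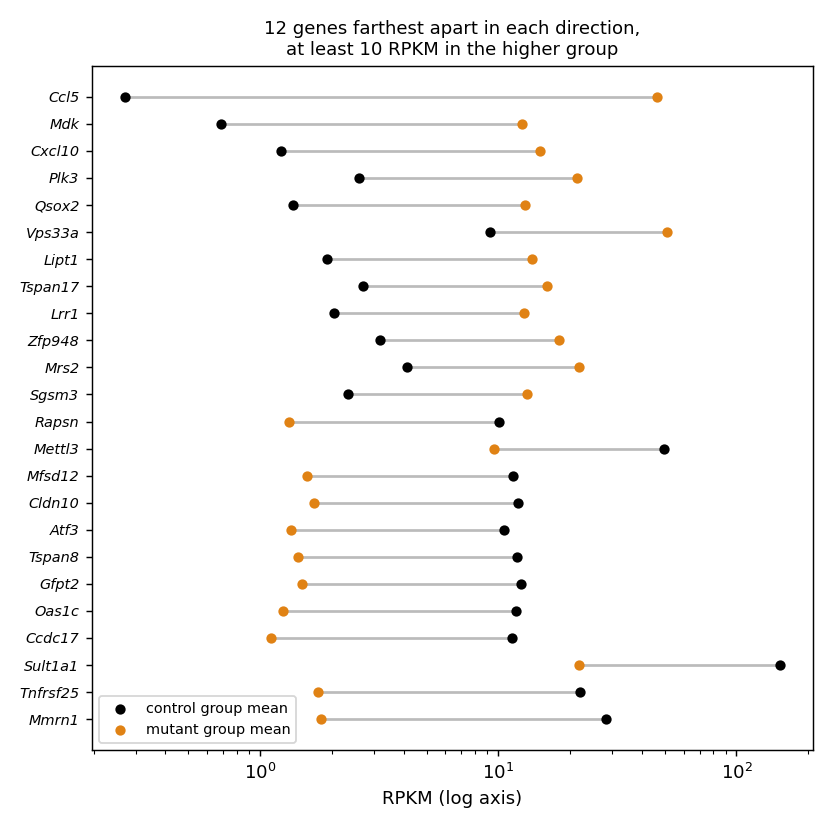
Control (black) and mutant (orange) group means in RPKM, on a logarithmic axis, of the 12 genes with the highest and the 12 with the lowest log2 ratio among genes with at least 10 RPKM in 1 of the groups, without error bars because the values are single group means. Ccl5 spans 0.270 to 46.6 RPKM, and Mmrn1 spans 28.3 to 1.81 RPKM.

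Of the 26 gene lists compared with random lists, 7 fell outside the central 95%, 5 of them above and 2 below. Lists of independently drawn genes would give 1.3. Genes of a fixed list can vary together, so 1.3 is not the number expected from chance between animals. Immediate early genes, which are induced within minutes by growth factors and by handling of cells, stood farthest from the random lists. Of 27 with reads, 22 were lower in the mutant mean and 14 were at least 2-fold lower, with a median log2 ratio of -1.05 (percentile 0). Fos, a subunit of the AP-1 transcription factor, was at 617 RPKM in controls and 171 RPKM in mutants. The stress-induced factor gene Atf3 was at 10.6 and 1.35 RPKM, Klf2 at 21.9 and 4.35 RPKM and Fosb at 11.6 and 2.44 RPKM. Heat shock chaperones, also part of cellular stress responses, had a median of 0.10 (percentile 85.6), with 11 of 16 higher, Hspa4l at 18.9 and 9.30 RPKM and Hsph1 at 12.6 and 20.7 RPKM in controls and mutants.

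Interferon response genes were higher in the mutant mean in 30 of 37, and 6 were at least 2-fold higher, with a median of 0.34 (percentile 99.9). Irf7, a transcription factor that amplifies type I interferon signalling, was at 27.0 RPKM in controls and 73.3 RPKM in mutants. Iigp1, an interferon-inducible GTPase gene, was at 11.3 and 29.96 RPKM, Oasl1 at 4.85 and 12.6 RPKM and Ifit1 at 10.8 and 18.0 RPKM. Both groups had received pIpC. Genes of double-stranded RNA sensing, a list of sensors and of genes downstream of them, had a median of 0.23 (percentile 91.3), inside the random range. Of 14, 10 were higher and 4 lower. The lower ones included the sensor genes Ddx58, at 9.12 and 8.74 RPKM, and Ifih1, at 13.5 and 10.9 RPKM. Among the higher ones Mavs, the mitochondrial adaptor of RIG-I-like receptors, was at 11.6 and 30.5 RPKM and Zbp1 at 8.63 and 13.5 RPKM.

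Genes of S phase and mitosis were higher in the mutant mean in 31 of 40, with a median of 0.37 (percentile 100). Ccne2, a cyclin of the G1 to S transition, was at 5.54 RPKM in controls and 21.5 RPKM in mutants. Tk1 and Rrm2, which supply nucleotides for replication, were at 51.8 and 151 RPKM and at 54.1 and 127 RPKM. The spindle checkpoint kinase gene Bub1 was at 6.44 and 14.6 RPKM. The 9 lower genes included the replication genes Pcna (119 and 93.2 RPKM), Mcm7 (128 and 110 RPKM) and Cdc45 (56.5 and 47.3 RPKM). Genes of quiescence and CDK inhibition were lower in 14 of 19, with a median of -0.22 (percentile 3.29), inside the central 95%. Their mean of -0.32 lay at percentile 0.60, outside it, and so did their median with a pseudocount of 0.1 (-0.27). Btg2, an antiproliferative gene, was at 58.8 and 22.1 RPKM and Egr1 at 120 and 52.6 RPKM, and both are also on the immediate early list. Cdkn1a, the CDK inhibitor p21, was at 12.2 and 14.2 RPKM.

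MYC targets and genes of ribosome biogenesis, compared as 1 list, were higher in 25 of 39. Their median was 0.19 (percentile 99.6) and none was 2-fold apart. By the mean the list was inside the central 95% (percentile 96.1). Ncl, which encodes nucleolin, was at 121 RPKM in controls and 198 RPKM in mutants, Grwd1 at 104 and 172 RPKM and Tsr1 at 18.0 and 29.8 RPKM, whereas the prohibitin gene Phb was at 51.6 and 30.7 RPKM. Myc itself was at 158 and 134 RPKM. Cytosolic ribosomal protein genes had a median of 0.03 (percentile 79.1), with Rplp2 at 83.8 and 123 RPKM and Rpl30 at 98.3 and 133 RPKM. Transcripts listed as m6A targets in blood cells had a median of 0.07 (percentile 64.8) and a mean of -0.04. Among these Nr4a2 was at 5.60 and 1.97 RPKM and Notch1 at 1.68 and 0.744 RPKM.

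**Figure D3:**
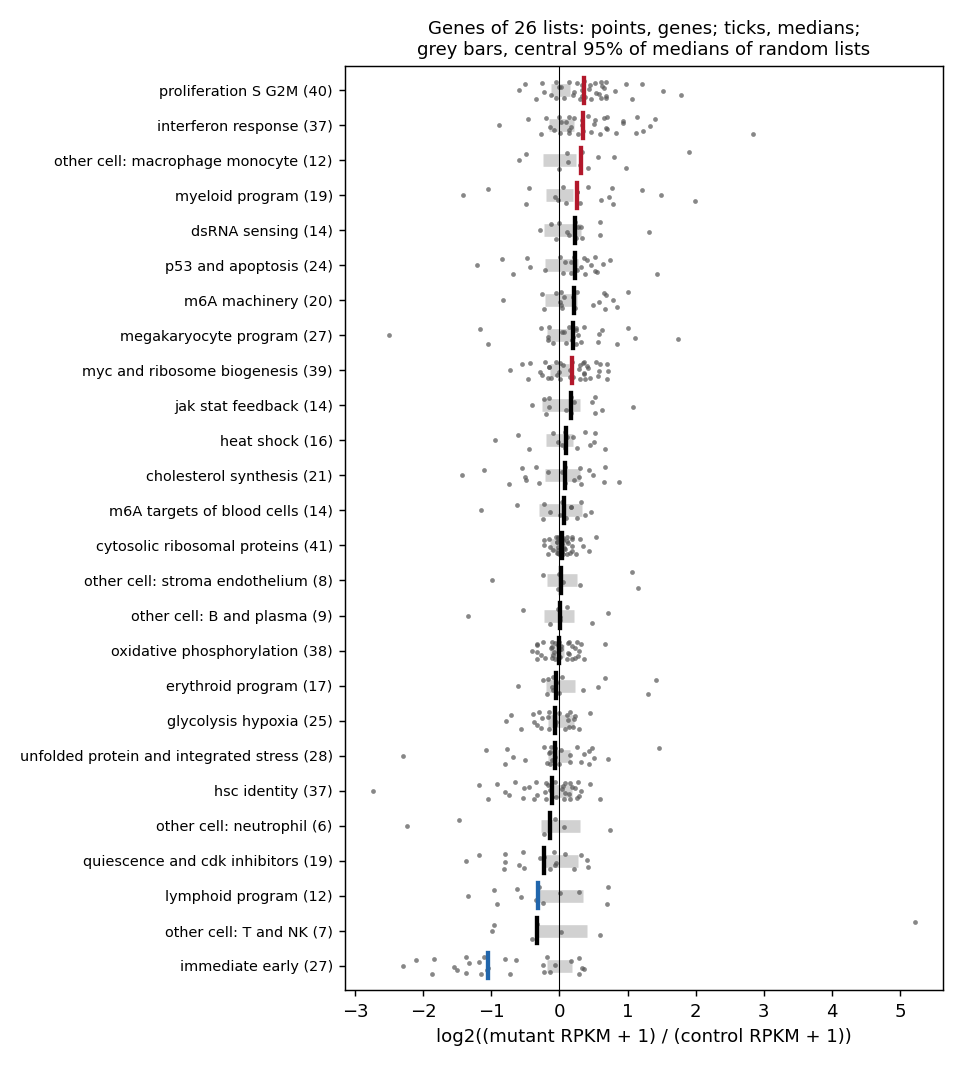
Log2((mutant RPKM + 1) / (control RPKM + 1)) of every gene with reads in 26 lists fixed before the data were examined; points are genes, vertical ticks are list medians (coloured where outside), grey bars span the central 95% of medians of 10000 matched random lists, and the number of genes follows each name. The median of the immediate early list is -1.05, and that of the S phase and mitosis list is 0.37.

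Genes of HSC identity were higher in 16 and lower in 21 of 37, with a median of -0.11 (percentile 5.45), inside the central 95%. Their mean of -0.23 lay outside it (percentile 0.06), and so did their median with a pseudocount of 0.1 (-0.15). Sult1a1 and Egr1 were among those at least 2-fold lower. Megakaryocyte genes had a median of 0.19 (percentile 96.0), inside the random range, and went both ways. Selp, the platelet adhesion molecule P-selectin, was at 20.05 and 69.2 RPKM, and Clec1b, a platelet receptor, at 6.35 and 0.297 RPKM. Itga2b, the integrin CD41, was at 19.7 and 22.4 RPKM.

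Myeloid genes were higher in 13 of 19, with a median of 0.26 (percentile 99.3). Cd68, a lysosomal glycoprotein of macrophages, was at 26.4 RPKM in controls and 108 RPKM in mutants, and Plac8 was at 90.5 and 255 RPKM. Mpo, the granule enzyme of myeloid progenitors, was low in both groups, at 0.0492 and 1.43 RPKM, and Ms4a3 was at 1.85 and 0.0691 RPKM. Lymphoid genes were lower in 8 of 12, with a median of -0.32 (percentile 1.91); by the mean the list was inside the central 95% (percentile 2.96). Lck was at 19.0 and 9.30 RPKM, Flt3 at 9.76 and 4.71 RPKM and Ltb at 146 and 242 RPKM. Igj was at 1.59 RPKM in controls, a value that equals whole reads of a single library, and at the offset in mutants. Erythroid genes had a median of -0.05 (percentile 22.9) and a mean of 0.16. The globin genes Hbb-b1 and Hbb-b2, near-identical copies whose reads may have been divided between them, were at 2.30 and 7.79 RPKM and at 7.32 and 19.4 RPKM.

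Markers of other cell types were compared in the same way. Macrophage and monocyte markers were higher in 10 of 12 with reads, with a median of 0.32 (percentile 99.4), the list outside the random range beside the myeloid genes. Hmox1 was at 2.03 RPKM in controls and 10.4 RPKM in mutants, whereas the complement genes C1qa, at 0.212 and 1.38 RPKM, and C1qb, at 1.87 and 0.904 RPKM, and the receptor gene Cd14, at the offset in controls and at 0.790 RPKM in mutants, stayed low in both. Most of the 12 were below 1 RPKM in both groups. Ly6c2 (0.05174 and 0.05179 RPKM) and Cd5l (0.0203 and 0.513 RPKM) counted as higher, each from whole reads of a single mutant library. Lyz2, the member with the highest level, was lower in the mutant mean, at 406 and 289 RPKM. The list median was 1.26 with a pseudocount of 0.1, which gives low genes more weight. Neutrophil markers had a median of -0.15 (percentile 9.57) over 6 genes and a mean of -0.53 that lay outside the central 95% (percentile 0.74), with Camp at 6.37 and 0.562 RPKM and S100a9 at 1.99 RPKM in controls and at the offset in mutants. T and natural killer cell markers had a median of -0.33 (percentile 2.70) over 7 genes and a mean of 0.45 (percentile 98.6, outside), with Ccl5 at a log2 ratio of 5.23. Nkg7 was at 124 and 62.3 RPKM. B and plasma cell markers had a median of 0.01 (percentile 54.1), which turned to -0.01 when the mutant column was divided by the median ratio, with Sdc1 at 3.14 and 5.80 RPKM. Stromal and endothelial markers had a median of 0.02 (percentile 51.3), with Pecam1 at 21.98 and 50.1 RPKM and Sparc at 1.34 and 3.90 RPKM.

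The remaining lists lay inside the random range. Genes of the p53 response and apoptosis had a median of 0.23 (percentile 94.5), with Tnfrsf10b at 0.262 and 2.39 RPKM and Plk2 at 36.7 and 15.2 RPKM. Feedback genes of JAK-STAT signalling had a median of 0.16 (percentile 86.0), with Pim2 at 57.4 and 123 RPKM and Pim1 at 2.30 and 4.08 RPKM. Genes of the unfolded protein and integrated stress responses had a median of -0.07 (percentile 22.8), and Chac1 was at 0.587 and 3.37 RPKM. Cholesterol synthesis had a median of 0.09 (percentile 63.0) and a mean of -0.06. Glycolysis and hypoxia genes had a median of -0.06 (percentile 21.4), with Aldoc at 79.9 and 46.1 RPKM and Hk2 at 6.64 and 3.66 RPKM. Oxidative phosphorylation had a median of -0.01 (percentile 74.2), a sign that turned with the mean (0.01) and when the columns were scaled to equal sums, with Uqcrfs1 at 109 and 175 RPKM and Uqcrc1 at 984 and 743 RPKM.

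Y-linked genes were detected in both groups: Ddx3y at 9.22 RPKM in controls and 3.49 RPKM in mutants, Eif2s3y at 22.5 and 12.3 RPKM, Uty at 1.83 and 0.7001 RPKM and Kdm5d at 0.857 and 1.45 RPKM. Xist was at 2.26 and 1.94 RPKM and its antisense partner Tsix at 4.48 and 2.73 RPKM. How many animals of each sex a group held is not given in the sources used here. Of 12 basophil and mast cell markers, 3 had reads, and no row carried the symbol of a mitochondrially encoded transcript.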

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

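All settings except the pseudocount of 0.1 were chosen after seeing the data. With that pseudocount, genes at least 2-fold apart numbered 2855 (1508 higher and 1347 lower) in place of 1038, and without a pseudocount 3655 (1981 higher and 1674 lower), because genes of low RPKM then pass the threshold. The macrophage and monocyte list kept its side of the random range, with a median of 1.26 and 2.32 under these settings. Both settings enlarge the differences of low genes, and most members of this list with reads were below 1 RPKM in both groups. By the mean, the list of MYC targets and ribosome biogenesis (0.14) and the lymphoid list (-0.30) came inside the central 95%. The lists of HSC identity (-0.23), quiescence (-0.32), neutrophils (-0.53) and T and natural killer cells (0.45) came outside. In the T and natural killer cell list, only Ccl5 (5.23) was 2-fold apart, 4 of 7 genes were lower and the median was -0.33. In the neutrophil list, only Camp (-2.24) and S100a9 (-1.48) of 6 genes were 2-fold apart. These 2 means therefore rest on single members and do not show a shift of the whole list. For the other lists the cause was not tested. The medians of HSC identity and quiescence also lay outside with the pseudocount of 0.1 (-0.15 and -0.27) and with none (-0.15 and -0.28). With a minimum of 1 RPKM in at least 1 group, the macrophage and monocyte list had fewer than 5 members and dropped out, and the megakaryocyte list came outside (0.24). The number of lists outside was 7 or 9 at every setting run. Mettl3 stayed between -2.37 and -2.25. Of 526 values of the 88 named genes, 41 moved by over 1.5 times. These were 17 of 88 with the pseudocount of 0.1 and 24 of 88 with none. The rescalings moved 0, and leaving out genes cannot change the values of those kept. None of those that had been 2-fold apart changed sign. That result was fixed in advance, because a pseudocount keeps the sign of a difference and the rescalings were small. Leaving out genes carried by a single library gave 527 higher and 486 lower genes. No paired analysis was possible because the columns are group means without replicate numbers. Not run, because they need counts or values per library, were the other normalizations, count filters, DESeq2, voom, robust and threshold settings, covariates, leaving out replicates, camera with an estimated correlation, fry, and the minimum in 3 libraries. If a step is 1 read, 1 RPKM on 1 kb is 19.6 reads at the smallest library size. Whether depth limits the values of low genes was not tested.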

Other observations

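All groups and tests in this part were chosen after the values were seen, apart from the marker lists, which were fixed before. Glutathione S-transferase genes, which conjugate electrophiles, were lower in the mutant mean in 14 of 18 with reads, with a median log2 ratio of -0.37 (percentile 0.02 among random lists). Gstm5 was at 264 RPKM in controls and 138 RPKM in mutants, Gstm1 at 171 and 111 RPKM and Gstk1 at 94.6 and 54.4 RPKM, whereas Gsto2 was at 0.0399 and 6.01 RPKM. Aldehyde dehydrogenase genes were lower in 10 of 15, with a median of -0.24 (percentile 1.58) and a mean of -0.14 that lay inside the random range (percentile 10.3). Aldh1a1, a retinaldehyde dehydrogenase, was at 108 and 34.7 RPKM, and Aldh1b1 was at 1.73 and 7.39 RPKM. The sequences of Gstm genes are similar, and how shared reads were counted is not given in the sources used here.

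Interferon-inducible GTPase genes were higher in 13 of 17, with a median of 0.51 (percentile 99.96), although Iigp1 and 3 guanylate-binding protein genes also stand on the interferon list. Igtp was at 98.9 RPKM in controls and 201 RPKM in mutants and Irgm1 at 64.8 and 124 RPKM. GIMAP genes, GTPases of lymphocytes and HSCs, were higher in 7 of 8 with a median of 0.48 (percentile 99.3), and Gimap9 was at 39.6 and 98.9 RPKM. Chemokine genes went both ways, 6 at least 2-fold higher and 2 lower of 16 with reads, with a median of 0.15 (percentile 81.2) and a mean of 0.68 (percentile 100). Their median was 1.00 among genes with at least 1 RPKM in at least 1 group. Besides Ccl5 and Cxcl10, Ccl9 was at 0.699 and 3.86 RPKM, and Ccl4 was at 36.3 and 16.7 RPKM.

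The first 365 rows of the table were not in the order of the gene identifiers, whereas the other 22673 were. The basis of that order is not given in the sources used here, and these genes were not treated as a list of calls. Mettl3 stood in row 3. Of the 365, 159 were higher and 206 lower in the mutant mean, and the smallest difference was 0.86 on the log2 scale without a pseudocount. They held 8 of the 12 genes named as highest and 7 of the 12 named as lowest. Of the 28 immediate early genes, they held 3.

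The lower immediate early genes in the mutant mean were set against 3 technical explanations. A different scaling of the columns moves all genes alike, but the median log2 ratio of the list lay -1.08 from that of the 10478 other genes with at least 1 RPKM in both groups (0.02), which argues against scaling. A general stress response to isolation in the controls would have lowered the heat shock chaperones in mutants too. Their median was 0.10, but immediate early genes can respond without chaperones, so handling stays open. A single control library with high values also stays open: if the others were at the mutant mean, it would need 1508 RPKM of Fos, and the group means cannot show whether it did, nor whether loss of Mettl3 lowers these transcripts.

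Genes with reads in a single group may look switched on or off. Of 932 genes with reads in mutants only, the values of 601 (64.5%) were whole reads of 1 library, and of 512 with reads in controls only, 367 (71.7%), where chance matches would give 0.05 and 0.02. A single library therefore accounts for most of them when genes with few reads are included. Of those with at least 1 RPKM, it accounts for 12 of 71 in mutants only and 26 of 64 in controls only. The match asks for no read in any other library of the group. The rest therefore had reads in more than 1 library, and whether 1 library held most of them cannot be told. Among the first 365 rows, 45 genes had reads in mutants only and 0 of these came from a single library alone. This argues against 1 library as the only source there, while 1 library with most of the reads stays open. In the same rows, 99 genes had reads in controls only, of which 23 came from a single library alone. Among these were Igj, Sdcbp2 at 3.68 RPKM and Adh1 at 2.89 RPKM. A single library accounts for the 23, and its share in the others of the 99 cannot be told.

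Cd68 and Ccl5 could be higher in the mutant mean because other cells entered the sort, whose gate excluded lineage-positive cells. Cd68 was 81.5 RPKM higher, and the other 16 macrophage and monocyte markers, with or without reads, were higher by a median of 0.12 RPKM. Of these only Hmox1 was higher by at least 0.1 of the Cd68 difference. Lyz2, another of them, was at 406 RPKM in controls and 289 RPKM in mutants, a level that would hide a small share. Ccl5 was 46.3 RPKM higher, and 0 of the other 14 T and natural killer cell markers were higher by at least 0.1 of that difference. The 14 markers, with or without reads, differed by a median of -0.0056 RPKM. Most of them had no reads in either group, so this median reflects the group offsets and not a difference in expression. Nkg7 and Lck, 2 of these markers, were lower in the mutant mean. These values argue against macrophages and against T or natural killer cells as the whole source; altered expression within the sorted HSCs stays open as a hypothesis, as does a single library with a high value.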
